A study of Mus musculus with 4 samples.

How the data were processed

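The data are chromatin immunoprecipitation sequencing (ChIP-seq) libraries from mouse B cells. Per the labels' protocols, B cells were isolated from spleens of mice aged 6 to 14 weeks by depletion of CD43-positive cells and cultured for 2 days with LPS (25 µg/ml) together with either dextran-coupled antibody to IgD (2.5 ng/ml) or IL-4 (5 ng/ml). Native chromatin was digested to mononucleosomes with MNase, and the libraries were amplified for 18 PCR cycles, size-selected near 220 bp and sequenced for 36 cycles, per the labels' protocols. The series holds 4 samples. The 2 samples whose antibody is labelled H3K4, 1 from PA1-knockout and 1 from wild-type B cells, were analysed. Their labels do not say which methylation state of H3K4 was precipitated or which of the stimuli was used. The other 2 samples, labelled for LPS with dextran, were not analysed here.

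The deposited files hold 1 line per mapped read, with its position, strand and a match descriptor, and no normalized value. The authors' processing used mm9 and SICER, per the submitters' processing notes, which give neither their roles nor versions. The aligner is not given in the sources used here. Every line of both files spans 25 bases, and no position and strand occurs more than 1 time within a file, so repeated reads were already absent from the deposited files. For reads with 1 mismatch, the descriptor's letter equalled the NCBIM37 base (the assembly that mm9 also is) in 100% of cases when positions were read as 1-based, so they were used as 1-based. The knockout file held 5260401 reads and the wild-type file 5539549. With reads stored this way, strong sites are compressed slightly; the promoter with the most reads in 1 library filled 18.6% of its positions.

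The 5′ end of each read was moved 75 bp into the fragment. Reads were counted within 1 kb either side of 1 transcription start site (TSS) per protein-coding gene of GENCODE vM1, namely the annotated TSS with the most reads in both libraries combined. This choice was made again for each alternative that changed the counts. Genes with 50 or more reads in the 2 libraries combined were compared, which left 12186 of 22367. Libraries were scaled by the trimmed mean of M values (TMM; trims of 30% on the ratio and 5% on the level), and values are given as normalized RPM (reads per 1000000 nuclear reads after scaling) or as the ratio of knockout to wild type. Each ratio has an exact conditional binomial (Clopper-Pearson) 95% interval. With 1 library per genotype there is no replicate check and no test between genotypes. Except as given next, intervals cover counting error only and compare these 2 libraries, since PCR reads without molecular identifiers are not independent molecules. Intervals on the share of islands or promoters that met a rule treat these as independent, although neighbours can lie in the same stretch of the genome. The interval on the difference between weak and strong promoters came from resampling promoters. A promoter was counted as higher or lower when its ratio was at least 1.5-fold and its interval excluded 1. The number expected from counting error alone came from 100 simulations.

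Islands of enrichment were called on both libraries together from 200 bp windows with a Poisson probability under 1e-05, over an effective genome share of 80%, joined across gaps of up to 200 bp and kept at 20 or more reads. Promoter islands lay within 1 kb of a TSS, and distal islands lay over 5 kb from any TSS. For the immunoglobulin heavy chain (Igh) constant genes, a unit ran from 10 kb upstream of each gene's 5′ end, shortened where it met the gene before it, to its 3′ end. It was meant to take in the I exon promoter and the switch region, but whether 10 kb reaches both was not checked gene by gene. Ighg3, Ighg2b and Ighe carry other names in GENCODE vM1 (AI324046, Ighg and Gm900). The first pair was placed by its neighbours, and the last by its synonym, in the RefSeq gene table of GRCm38.p6. Ighd and Igha were not analysed here. PA1 (Pagr1a) was matched to 2900092E17Rik by the same table.

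Before the data were examined, 15 gene lists were fixed: the PA1-PTIP-MLL3/4 complex, other H3K4 methyltransferase and demethylase genes, class switch recombination machinery, B cell identity, plasma cell differentiation, B cell activation and NF-kB, IL-4 and STAT6 response, interferon response, proliferation, housekeeping genes, T and NK cell markers, myeloid markers, erythroid and stromal markers, silent developmental genes and immunoglobulin constant genes. A list's median log2 ratio, minus that of all tested promoters, was placed among 10000 random lists of the same size matched on reads. The percentile describes these libraries and is not a p-value. The genes to be named were also fixed by rule. They were PA1 and Paxip1, the Igh constant genes, the 12 higher and 12 lower promoters whose interval bound nearest to 1 was farthest from it, the 5 promoters with the most reads, and the 2 highest and 2 lowest members of each list.

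The counting and calling steps were tested on simulated data built from the real promoters' reads. Of promoters changed 2-fold, 97.0% were recovered (97 of 100), of those changed 3-fold 99 of 99, and 0.648% of 11881 unchanged promoters were called. The simulated counts held counting error and a single scale difference, with no GC or level trend. These rates therefore do not cover such differences between the real libraries. Alternatives covered scaling (total reads, median of ratios, reads outside islands and promoters), window, fragment shift, read minimum, fold threshold, equal depth, island settings, and smooth trends on GC content and on signal level (lowess, span 30%). Removal of both trends together and a correction for filled positions were added after the data had been seen. The planned comparison with all reads as deposited was void, since the files hold 1 read per position and strand. Positions where reads differ from the reference were taken from the match descriptor. They needed 3 or more mismatching reads in at least 1 library and 3 or more reads in each. A position counted for 1 library when 80% or more of its reads and none of the other library's mismatched. The software was Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6, pysam 0.24.0 and Matplotlib 3.10.9, and samtools 1.23.1.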

Results

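H3K4 ChIP-seq signal was compared between activated splenic B cells of PA1-knockout and wild-type mice. PA1 is a partner of PTIP in the complex that holds the H3K4 methyltransferases MLL3 and MLL4, and the series asks how histone modifications depend on it during immunoglobulin class switching. The knockout library held 5259995 nuclear reads and the wild-type library 5539475, with 1 library per genotype, so every ratio below is knockout over wild type for these 2 libraries with a 95% interval for counting error alone. The 5 promoters with the most reads were those of Hjurp (overlapping Trpm8), Irf8, Inpp5d, Coro1a and Cytip, with 638 to 744 reads in each library. None of these 5 passed the 1.5-fold threshold, with ratios from 0.989 at Irf8, a transcription factor of the B and myeloid lineages, to 1.21 at Cytip; all 5 were below 1 when scaled to background. The fixed lists of marker genes for other cell types had low medians, 1 knockout and 2 wild-type reads per promoter for T and NK cell genes and 2 and 2 for myeloid genes, although single members had more, such as Pecam1 with 389 and 352 and Gata3 with 166 and 187.

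The promoter of the targeted gene was lower in the knockout library. PA1 (2900092E17Rik, ENSMUSG00000030680.2) lies on the minus strand of chromosome 7, with its TSS at position 134159998 in mm9. Its promoter held 114 knockout and 261 wild-type reads, a ratio of 0.498 (0.396 to 0.624), and with a 2 kb window the ratio was 0.657. Across the gene with 2 kb on either side (134142996 to 134165841), 369 and 563 reads gave a ratio of 0.748 (0.654 to 0.854). This span mixes the promoter with a separate peak that was not clearly lower. There, 134157496 to 134157995 held 88 knockout and 114 wild-type reads, and 134157996 to 134158495 held 82 and 68. Paxip1, which encodes PTIP (chromosome 5, TSS 28117879), had a ratio of 0.696 (0.595 to 0.812; 267 and 438 reads), under the 1.5-fold threshold, and passed it at 0.642 when scaled to total reads, at 0.556 when scaled to background and at 0.660 with the level trend removed. The labels do not say which part of PA1 was deleted, and a histone mark outside the deleted part does not check the genotype label. PA1 lies in a 10 Mb block of the genome with 3 positions where the knockout library alone mismatched the reference, and Paxip1 in a block with 6 where the wild-type library alone did.

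Over the Igh constant region, signal at the Ighg3 and Ighg2b units was lower in the knockout library, while signal at the Ighm unit was not, except when scaled to background. These units were meant to take in the switch regions and the germline promoters whose transcription precedes switching to IgG3 and IgG2b. The Ighg3 unit (chromosome 12, 114597876 to 114609443) held 448 knockout and 1136 wild-type reads, a ratio of 0.450 (0.403 to 0.503). The Ighg2b unit (114544600 to 114556144) held 251 and 587 reads, a ratio of 0.488 (0.419 to 0.567). The Ighm unit (114659078 to 114670941), which holds the donor switch region, had 1677 and 1744 reads and a ratio of 1.10 (1.03 to 1.17).

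**Figure D1:**
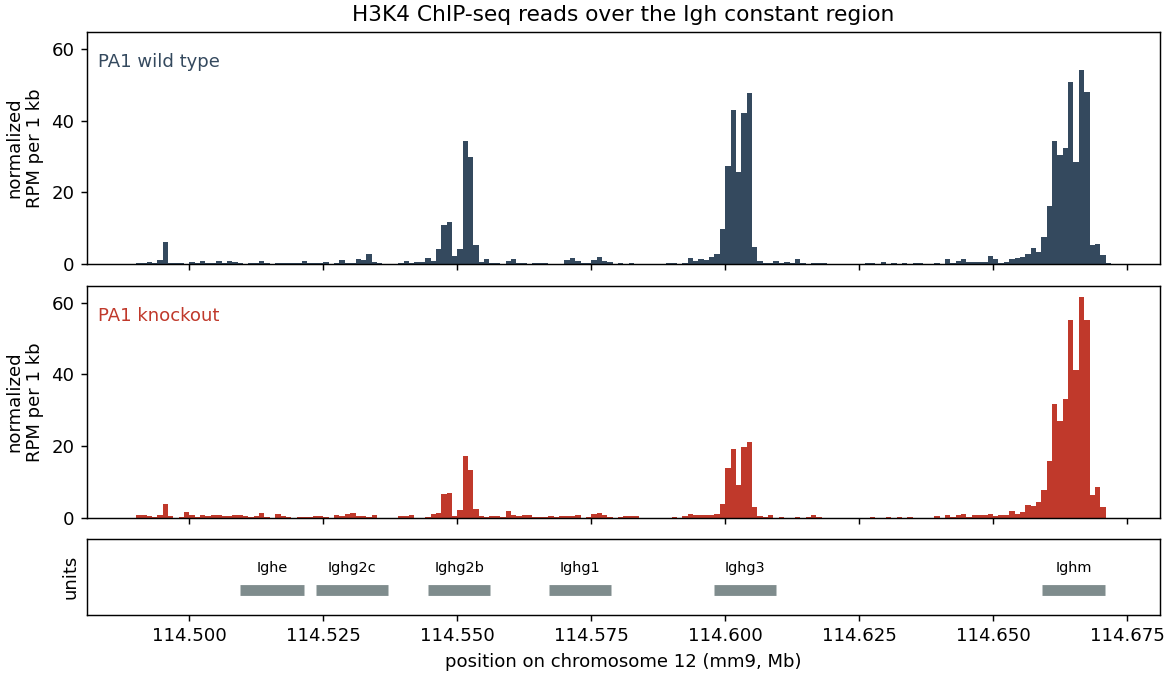
Normalized RPM in 1 kb bins (vertical axes) along the Igh constant region of chromosome 12 in mm9 (horizontal axis, Mb) for the wild-type (upper) and knockout (middle) libraries, 1 library each, with the counted units as grey bars below. The peaks in the Ighg3 and Ighg2b units are lower in the knockout library, with unit ratios of 0.450 and 0.488, whereas the Ighm unit has a ratio of 1.10, or 0.877 when scaled to background.

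Most reads of the Ighg3 unit fell in a single 6000 bp island (114599201 to 114605200), with 428 knockout and 1098 wild-type reads and a ratio of 0.445 (0.397 to 0.498). In the Ighg2b unit, a 2800 bp island (114550601 to 114553400) had a ratio of 0.474 (0.393 to 0.570) and a 2000 bp island (114546601 to 114548600) a ratio of 0.545 (0.399 to 0.738). Set against Ighm within each library, the log2 ratio of ratios was -1.29 (-1.47 to -1.10) for Ighg3 and -1.17 (-1.40 to -0.93) for Ighg2b. Ighg3 and Ighg2b differed from each other by -0.12 (-0.38 to 0.15), which is within counting error. The other units held few reads in either library. The Ighg1 unit ended at 114578734, and whether it reached the Ighg1 I exon promoter was not checked. Upstream of it, bins such as 114584001 to 114585000 held 0 reads in both libraries, and whether reads can map there was not tested. Ighg1 had 28 and 46 reads and a ratio of 0.695 (0.418 to 1.14), Ighg2c had 28 and 50 reads and a ratio of 0.639 (0.387 to 1.03), and Ighe had 24 and 22 reads and a ratio of 1.25 (0.669 to 2.33), so each interval included 1. Set against Ighm, Ighg2c had a log2 ratio of ratios of -0.78 (-1.45 to -0.11), but the Ighg2c ratio was 0.966 with 5 kb of upstream sequence in place of 10 kb. Scaled to reads outside islands and promoters, the Ighm ratio turned to 0.877, with Ighg3 at 0.360 and Ighg2b at 0.390, so that the direction at Ighm depended on the scaling and the direction at Ighg3 and Ighg2b did not. On that scale Ighe was at 0.995 (0.534 to 1.86), Ighg1 at 0.555 (0.334 to 0.907) and Ighg2c at 0.511 (0.310 to 0.827), and scaled to total reads Ighg2c was at 0.590 (0.357 to 0.955), so whether Ighg1 and Ighg2c differed depended on the scaling. Reads outside islands across the region were also lower in the knockout library, at 246 against 385.

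Across the genome, 81 promoters were higher and 597 lower in the knockout library, of 12186 compared. Counting error alone gave medians of 28.5 higher and 30.5 lower, and at most 45 and 42, in 100 simulations. The lower promoters were mostly weakly marked, with a median of 115 reads in both libraries combined against 462 for all tested promoters and 180 for the higher ones. The median log2 ratio went from -0.43 for promoters with 50 to 100 reads to 0.10 for those with 800 or more, and from 0.27 where GC content was under 45% to -0.29 where it was 65% or more. Removing both trends left 140 higher and 144 lower promoters, of which 51 and 140 were among those above. Scaling to reads outside islands and promoters shifted the median log2 ratio of all tested promoters by -0.32 and gave 17 higher and 2152 lower.

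Among the higher promoters, the genes with the most conservative ratios included a pair of G protein signalling regulators on chromosome 1 and the J chain. Rgs13 (TSS 146024502) had 84 knockout and 14 wild-type reads, a ratio of 6.85 (3.86 to 13.1). Nearby, Rgs1 (TSS 146096157) had 83 and 40 reads and a ratio of 2.37 (1.61 to 3.55). Igj, which encodes the J chain of secreted IgM and IgA (chromosome 5, TSS 88955665), had 182 and 64 reads and a ratio of 3.25 (2.43 to 4.39). Ctla4, an inhibitory receptor best known from T cells (chromosome 1, TSS 60966015), had 195 and 70 reads and a ratio of 3.18 (2.41 to 4.24). The others by the same rule were 4930481A15Rik at 2.14, the apoptosis inhibitor Birc2 at 2.17, the ubiquitin ligase subunit Asb2 at 2.70, the inflammatory caspase Casp4 at 1.90, the chemokine receptor Cxcr7 at 1.95, D18Ertd653e at 1.75, the scavenger receptor Cd36 at 1.78 and the haem synthesis enzyme Alad at 1.61. Cd36 and Alad were below the threshold when both trends were removed, at 1.31 and 1.49, Casp4 with the GC trend removed, at 1.48, and Birc2 with the 2 kb window, at 1.45. Scaled to background, D18Ertd653e, Cd36 and Alad were below it, at 1.40, 1.42 and 1.29, and Alad also when scaled to total reads, at 1.49. Rgs13 and Asb2 had fewer than 50 reads with a 500 bp window.

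The lower promoters with the most conservative ratios were led by genes of chromosome 7, which also carries PA1. Trim12a (TSS 111463857) had no knockout read and 59 wild-type reads, with an upper bound of 0.0736 on the ratio, and Trim30d (TSS 111656339), of the same TRIM gene cluster, had 1 and 90 reads and a ratio of 0.0127 (0.000318 to 0.0725). Trim6 (TSS 111367307) had a ratio of 0.201 (0.0992 to 0.375). Sult2b1, a steroid sulfotransferase (TSS 52997853), had 5 and 150 reads and a ratio of 0.0380 (0.0122 to 0.0908). Also on chromosome 7 were the short-chain fatty acid receptor Ffar2 at 0.245, the apolipoprotein Apoe at 0.314 and the adhesion molecule Ceacam1 at 0.347. On other chromosomes, the lower promoters were Rapgefl1 at 0.150, the guidance ligand Slit3 at 0.137, the calcium channel Ryr2 at 0.143, Rbm44 at 0.217 and the hedgehog pathway receptor Smo at 0.273. All 12 were still counted as lower with both trends removed, but Rapgefl1 was not with a window of 2 kb, at 0.864, or 500 bp, at 0.770. The TSS was chosen again for each window, so these values need not be of the same Rapgefl1 TSS. With a 500 bp window Trim12a, Slit3, Ryr2, Rbm44 and Smo had fewer than 50 reads and were not compared, and the same held for Rbm44 with no fragment shift or at equal depth. On chromosome 7, 55 positions mismatched the reference in the knockout library alone and 1 in the wild-type library alone.

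**Figure D2:**
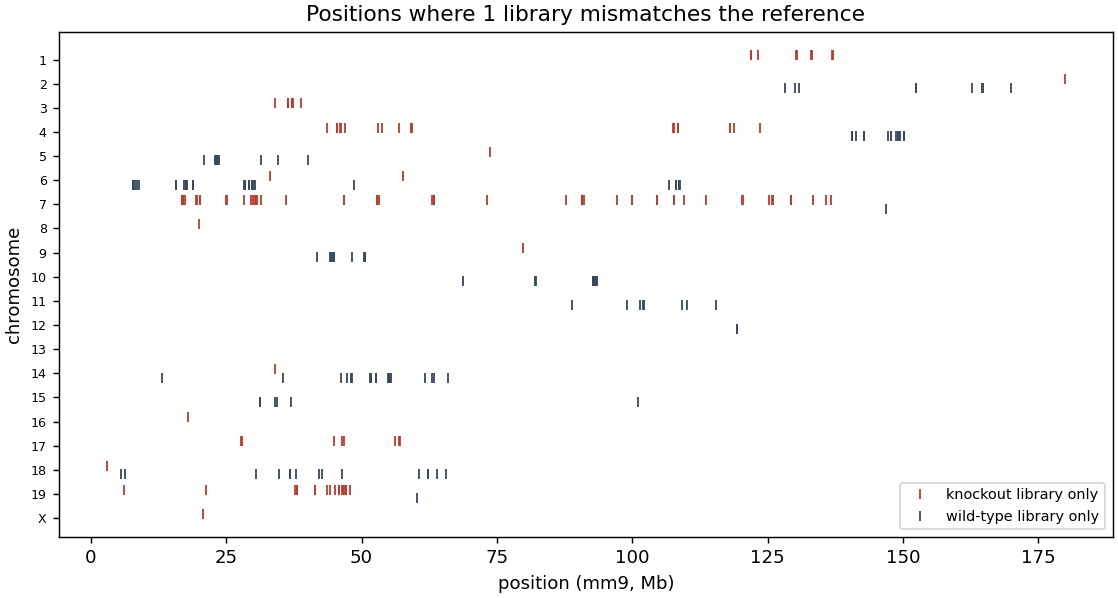
Positions in mm9 (horizontal axis, Mb) on each chromosome (vertical axis) where reads of 1 library mismatched the reference and those of the other did not, in red for the knockout (130) and dark blue for the wild-type library (159). Chromosome 7 holds 55 knockout-only positions and 1 wild-type-only position.

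**Figure D3:**
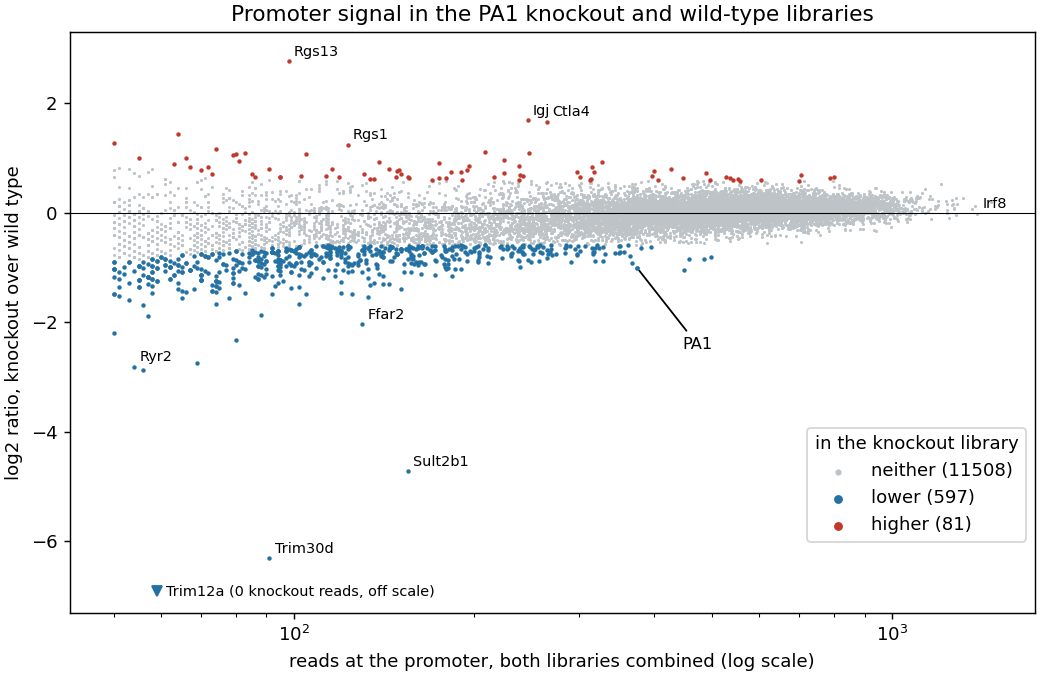
Each point is 1 of the 12186 promoters, placed by its reads in both libraries combined (horizontal, log scale) and its log2 ratio of knockout over wild type (vertical), and coloured by whether it was higher (81), lower (597) or neither (11508). The lower promoters lie mostly to the left, with a median of 115 reads, and Trim12a, with 0 knockout reads, is drawn as a triangle off the scale.

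Genes that carry out class switch recombination did not differ between the libraries beyond the threshold. Of 22 members, 0 were higher and 0 lower, and the list's median log2 ratio was 0.09 above that of all promoters, at percentile 88.6 of matched random lists. Its extremes were Xrcc4 at 1.24 and Lig4 at 1.22, both of end joining, and the uracil glycosylase Ung at 0.766 and H2afx at 0.970; Ung was lower, at 0.612 (0.491 to 0.762), when scaled to background. The 22 B cell identity genes likewise had 0 higher and 0 lower (percentile 59.6), from Fcer2a at 0.779 and Spib at 0.851 to Syk (annotated as Sykb) at 1.23 and Bach2 at 1.33. Its median was 0.10 relative to all promoters, but turned to -0.03 with the GC trend removed and -0.11 with both trends removed, each at percentile 0, and Fcer2a was lower at 0.661 with both removed and at 0.622 when scaled to background.

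The IL-4 and STAT6 response list stood lowest in the knockout library. The labels do not say whether these cultures received IL-4. The Ighg1 and Ighe units held few reads, but the Ighg1 unit may stop short of its I exon promoter, so this does not settle the stimulus. The list's member Ccl22 had 13 knockout and 16 wild-type reads. The list's median log2 ratio was -0.21 relative to all promoters (-0.29 to -0.06 for counting error), below the 10000 matched random lists (percentile 0). None of its 12 tested members passed the 1.5-fold threshold. The suppressors of cytokine signalling Socs3 and Socs1 had ratios of 0.714 (0.594 to 0.856) and 0.742 (0.596 to 0.921), passing the threshold at 0.570 and 0.593 when scaled to background, and Socs3 at 0.659 when scaled to total reads. With both trends removed they stood at 0.828 (0.689 to 0.992) and 0.920 (0.739 to 1.14), the latter within counting error. The highest members were Xbp1 at 1.12 and Batf at 1.10. Fcer2a, Xbp1 and Batf also belong to other lists here. The list's median remained negative, with percentiles from 0 to 0.01, under each alternative run on it.

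The genes of the PA1-PTIP-MLL3/4 complex had a median of -0.14 relative to all promoters (percentile 0.71), with PA1 as the 1 lower member of 10. This placing includes the targeted gene itself, and no percentile was computed without it. Of the other members the middle one was Dpy30, at a log2 ratio of -0.08. The central 95% of random lists of 10 ran from -0.10 to 0.16 relative to all promoters. Next to PA1 and Paxip1 at the lower end, Rbbp5 and Ash2l, shared subunits of H3K4 methyltransferase complexes, were highest at 1.21 and 1.16. With the GC trend removed the complex's median turned to 0.04 (percentile 59.3). Among the other H3K4 methyltransferase and demethylase genes, 0 of 10 passed the threshold (percentile 40.4), from Setd1b at 0.848 and Kdm5b at 0.874 to Cxxc1 at 1.10 and Kdm1a at 1.22.

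Plasma cell genes had a median of 0.16 (percentile 93.6), with Igj as the 1 higher member of 9. Prdm1, the master regulator of plasma cell differentiation, had a ratio of 1.36 (1.17 to 1.60), Irf4 0.930 and Sdc1 0.724. Scaled to background, Sdc1 was lower at 0.579 (0.477 to 0.701). With a 2 kb window this list lay above the random lists, at 0.34 (percentile 100), and with the GC trend removed at 0.02 (percentile 24.1). In the activation and NF-kB list, 1 of 22 members was higher, the early activation marker Cd69 at 1.56 (1.35 to 1.81), and 1 lower, the cytokine gene Il6 at 0.598 (0.470 to 0.758), with Tlr4 at 1.26 and Nfkbia at 0.792 next (percentile 60.9). This list's median was 0.07, but -0.01 with a 2 kb window (percentile 2.5) and -0.01 with both trends removed (percentile 34.7). Nfkbia was lower at 0.633 when scaled to background. Cd69 was below the threshold, at 1.16 to 1.47, with total reads or background scaling, a 2 kb window, or the GC trend, the level trend or both removed, and Il6 was within it at 0.721 with a 500 bp window. The interferon response list had 0 of 13 past the threshold and a median of 0.12 (percentile 95.04), from Rsad2 at 0.898 and Irf1 at 0.957 to Oas1a at 1.28 and Isg15 at 1.41. Isg15 was higher with a 500 bp window, at 1.58 (1.23 to 2.02), and Oas1a with the level trend removed, at 1.62 (1.11 to 2.37). Its percentile was 98.6 with a 2 kb window, 99.9 with the level trend removed and 65.4 with both trends removed.

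In the proliferation list 1 of 14 members was lower, Ccne1 at 0.666 (0.518 to 0.852), which did not pass, at 0.6701 to 0.853, with the 2 kb or 500 bp window, no fragment shift, a minimum of 20 reads, or the GC trend, the level trend or both removed. Cdk1 at 0.876, Ccna2 at 1.19 and Top2a at 1.20 were its other extremes, and the list lay at percentile 36.5. Of 17 housekeeping genes 0 passed (percentile 48.3), from Eef1a1 at 0.852 and Actb at 0.960 to Tbp at 1.22 and Pgk1 at 1.23. Scaled to background, the members named above as highest in these lists that turned below 1 were Tbp, Pgk1, Ccna2, Top2a, Lig4, Xrcc4, Syk, Rbbp5, Ash2l, Kdm1a, Cxxc1, Xbp1 and Batf, and Gata3 did so too. The T and NK cell list had 3 members with enough reads, Tbx21 at 0.771, Lck at 0.940 and Gata3 at 1.01 (percentile 55.8), and the erythroid and stromal list had 4, from Col1a1 at 0.943 and Klf1 at 0.973 to Pecam1 at 1.26 and Epcam at 1.29 (percentile 96.8). The erythroid and stromal median was 0.15, but -0.04 with a 2 kb window (percentile 78). The myeloid list had Cebpa at 0.707 and Itgam at 1.48, neither past the threshold, although Itgam was higher with the level trend or both trends removed, at 2.04 and 1.77. Epcam was higher in those settings, at 1.60 and 1.59, and with a 500 bp window, at 1.69. Cebpa was lower, at 0.565 to 0.652, with total reads or background scaling, a 2 kb window or no fragment shift, and Tbx21 was lower at 0.616 with background scaling. The silent developmental list had Pax6 at 0.744 and Olig2 at 0.351 (0.167 to 0.685), which was lower but had fewer than 50 reads with a 500 bp window. Pax6 was lower at 0.594 when scaled to background. In the immunoglobulin constant gene list only 2 genes, Ighg2c and Ighe, were matched, and neither promoter window reached 50 reads. Promoter windows of its other members, such as Ighm and Ighg3, were not counted.

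**Figure D4:**
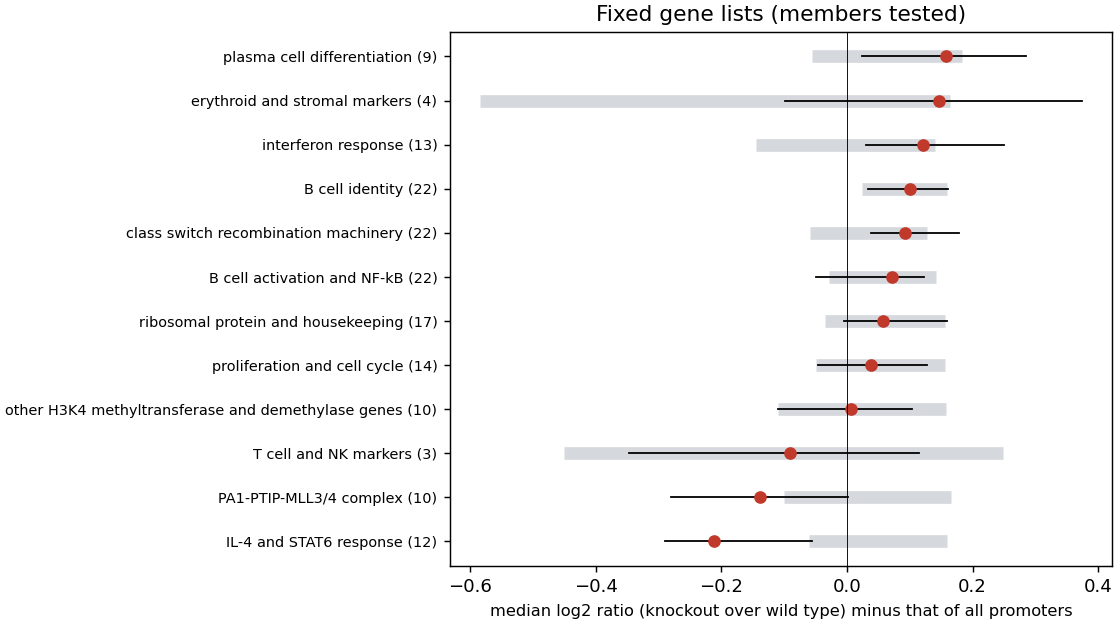
Median log2 ratio of knockout over wild type for each fixed gene list, minus that of all tested promoters (red points, horizontal axis), with the number of tested members in parentheses, the 95% counting interval as a black line and the central 95% of 10000 random lists matched on reads as a grey bar. The IL-4 and STAT6 response list at -0.21 and the PA1-PTIP-MLL3/4 list at -0.14 lie outside the grey bars, the latter with PA1 itself among its members.

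A slightly smaller share of knockout reads fell at enriched sites. Reads within 1 kb of a TSS made up 50.8% of the knockout library (50.8 to 50.8, exact binomial) and 54.1% of the wild-type library (54.1 to 54.2), and reads in islands 74.2% (74.1 to 74.2) and 77.2% (77.2 to 77.3). Promoter islands (13617, median 1800 bp) and distal islands (8507, median 600 bp) had nearly the same median log2 ratio, 0.02 and -0.01. Among promoter islands 179 were higher and 700 lower, and among distal islands 511 were higher and 441 lower. The distal median lay -0.02 from the promoter median, but 0.23 above it when promoter islands were matched to distal ones on reads. Islands are not replicates, and this difference turned with the level of signal compared.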

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

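The tests in this part were chosen after the results they bear on had been seen, except for the share of islands as low as the Ighg3 island; background scaling and the removal of the GC trend or of the level trend were planned as settings, and their use as tests of causes came after. In data outside the promoter and island counts, 3 signals of the knockout library stood above the wild-type library. Positions with reference mismatches in the knockout library alone numbered 55 on chromosome 7, against 1 for the wild-type library alone. On chromosome 19 there were 19, against 1. Such positions also leaned the other way, with 47 in the wild-type library alone against 2 on chromosome 6, 23 against 1 on chromosome 14 and 15 against 1 on chromosome 18. Mitochondrial reads made up 77.2 per 1000000 nuclear reads in the knockout library and 13.4 in the wild-type library (406 and 74 reads), a ratio of 5.78 (4.50 to 7.51).

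The 4818 positions examined had 3 or more mismatching reads in at least 1 library. At 425 of them, 80% or more of the reads mismatched in both libraries. Library-specific mismatches numbered 130 for the knockout and 159 for the wild-type library. Of neighbouring positions, 95.2% belonged to the same library, against at most 61.1% in 10000 shuffles, which argues against random sequencing errors and is consistent with mice of different strain background. A block of 10 Mb counted for 1 library with 3 or more positions of that library and none of the other. Islands of 50 or more reads whose interval lay beyond a 4-fold difference made up 8 of 1908 (0.419%, 0.181 to 0.824) in knockout blocks. Of these, 6 were higher and 2 lower in the knockout library. They made up 1 of 1546 (0.0647%, 0.00164 to 0.360) in wild-type blocks and 10 of 15589 (0.0641%, 0.0308 to 0.118) elsewhere. Strain background in the knockout blocks may account for some of the largest differences, but the wild-type blocks showed no such excess. Promoters at least 2-fold lower with both trends removed made up 8 of 891 on chromosome 7 (0.898%, 0.388 to 1.76) and 17 of 11295 elsewhere (0.151%, 0.0877 to 0.241). PA1 also lies on chromosome 7, where knockout-only positions ran from 16824816 to 136735746. An effect of PA1 loss on these promoters was not tested and cannot be told apart from a strain difference here. The island at the Trim30d promoter (111655601 to 111656400) lay outside the blocks counted above.

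The Ighg3 and Ighg2b units were lower in the knockout library, at 0.450 and 0.488, and Ighm was not, at 1.10 (0.877 when scaled to background). Divided by the median ratio of islands with like reads and GC content, the Ighg3 island stood at 0.435 (0.388 to 0.487) and the Ighg2b island at 0.452 (0.375 to 0.544), which argues against GC or level trends as the whole cause. As low were 1 of 2881 such islands for Ighg2b (0.0347%, up to 0.193%), which argues against these trends there, and 1 of 490 for Ighg3 (0.204%, up to 1.13%), where the matched islands are too few to exclude a rare tail. Reads lost to scattered single-base strain variants would leave many mismatches among those that mapped. The Ighg3 unit had 8.93 per 100 knockout reads (6.38 to 12.2) against 6.87 in the wild-type library, and Ighg2b 9.52 against 6.46. These rates were below the level set for this test, which was chosen afterwards from an assumed loss of reads. A deletion or a diverged stretch could remove reads without leaving mismatches, so such losses stay open. Fewer DNA copies of the whole region as the only cause would lower the Ighg3 unit no more than reads outside islands. However, on the background scale the unit stood at 0.360 (0.322 to 0.402) and those reads at 0.583 (0.495 to 0.686). Fewer DNA copies as part of the cause stay open, because reads over 5 kb from islands stood at 0.659 (0.541 to 0.802), which excludes both 0.5 and 1. In the flanks, reads over 1 kb from islands were counted, so the distance rule differs. They stood at 0.750 (0.656 to 0.856) in the 500 kb beyond Ighe, which overlaps the region's interval. Beyond Ighm they stood at 1.03 (0.815 to 1.299), which does not. An effect of PA1 loss and a different response of the 2 cultures stay open as untested.

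More promoters were lower than higher in the knockout library, 597 against 81. Removing the GC trend left 456 and 38, a ratio of 12, and correcting for filled positions left 605 and 102, a ratio of 5.93, so neither was the whole cause. More background in the knockout library would raise weak promoters relative to strong ones, but promoters with fewer than 100 reads had a median log2 ratio that differed from that of promoters with 800 or more by -0.54 (-0.58 to -0.50). Added background therefore does not explain why weak promoters were lower. Its presence is not excluded, since these ratios were not adjusted for GC content. Reads in islands also made up 74.2% of the knockout library against 77.2% of the wild-type library. Removing the level trend centres the ratios at every level, so its 178 lower and 233 higher promoters do not decide between causes. A level-dependent difference between the immunoprecipitations and an effect of PA1 loss on weakly marked promoters stay open.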

How the results depend on the processing

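The GC and level trends removed together and the correction for filled positions were chosen after the data had been seen. Ighg3, Ighg2b and the PA1 promoter kept their direction under each alternative run on them, with Ighg3 from 0.360 to 0.450, Ighg2b from 0.390 to 0.515 and PA1 from 0.398 with background scaling to 0.657 with the 2 kb window, and the number of lists outside the central 95% of random lists was 2 or 3. The IL-4 and STAT6 list was outside it in each setting run on lists, the PA1-PTIP-MLL3/4 list with each scaling and read minimum run, plasma cell genes with the 2 kb window and the minimum of 1 read, interferon genes with the 2 kb window and the level trend removed, and B cell identity genes with the GC trend or both trends removed. For the promoters named above, 878 values under an alternative stayed within the counting interval, 58 moved outside it and 12 turned direction from a ratio whose interval excluded 1. Among the others, 42 crossed 1 from a ratio whose interval included 1. Where values moved or turned, the cause was not tested unless the setting itself gives it. Promoters higher and lower numbered 41 and 947 with total reads scaling and 17 and 2152 with background scaling, which add a single factor to every ratio. A 2-fold threshold left 13 and 162. The higher ones numbered 141 with a 500 bp window, 131 with a minimum of 1 read, 38 with the GC trend removed, 233 with the level trend removed and 140 with both removed, and the lower ones 178 and 144 in the last 2 settings. Ighm stood at 1.01 with total reads scaling, and with background scaling Ighm was 0.877, Ighg3 0.360 and Ighg2b 0.390. Among promoters whose interval excluded 1, background scaling turned Hjurp (0.913), Cytip (0.965), Syk (0.984), Rbbp5 (0.966), Lig4 (0.974), Xrcc4 (0.989), Ccna2 (0.951), Top2a (0.958), Tbp (0.972) and Pgk1 (0.986), and removing both trends turned Cytip (0.984) and Cebpa (1.03). The knockout and wild-type shares of reads at promoters were 62.7% and 65.4% with 2 kb windows and 50.7% and 54.0% with no shift. Their shares in islands were 74.0% and 77.0% with no shift, 72.1% and 74.9% at a Poisson threshold of 1e-08, and 74.5% and 77.6% with a 600 bp gap. The distal minus promoter median was 0.010 with 50 reads per island, -0.035 at 2 kb from a TSS and 0.23 with islands matched on reads. The PA1-PTIP-MLL3/4 list, which includes PA1 itself, stood at 0.043 with the GC trend removed and at 0.039 with both removed. Not run was the planned use of all reads as deposited, since the files hold 1 read per position and strand, and background scaling moves both island classes alike. Depth limits the Ighg1, Ighg2c and Ighe units, with 22 to 50 reads per library, and intervals of Ighg1 and Ighg2c excluded 1 with background scaling, as that of Ighg2c did with total reads scaling. No paired analysis was possible because each genotype has 1 library.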

Other observations

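Some distal islands, chosen after their values were seen, had ratios far from 1. An island on chromosome 4 (110579001 to 110579800), 212 kb from the nearest TSS (Agbl4), held 51 knockout and 0 wild-type reads, with a lower interval bound of 15.2 on the ratio, and another on chromosome 4 (57275401 to 57276200) held 50 and 0 reads. On chromosome 19, an island 5.7 kb from the Sgms1 TSS (32276601 to 32277800) held 111 and 4 reads, a ratio of 31.7 (12.03 to 118), and one near Neurl1a (47295201 to 47297800) 221 and 26 reads, a ratio of 9.70 (6.45 to 15.2). These 4 lie in 10 Mb blocks with positions that mismatched the reference in the knockout library alone, but others did not, such as an island on chromosome 10 (44432401 to 44434200) with 128 and 7 reads, a ratio of 20.9 (9.84 to 53.0). Of all islands of 50 or more reads more than 4-fold higher by their interval, 6 lay in such blocks, 1 in a block of wild-type-only positions and 8 in neither. In the opposite direction, an island on chromosome 7 (113787001 to 113788600) held 22 and 205 reads, a ratio of 0.122 (0.0751 to 0.191), and one 156 kb from the Cacna1e TSS on chromosome 1 (156729401 to 156732200) held 172 and 444 reads, a ratio of 0.442 (0.369 to 0.528).

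The labels leave open which stimulus these 2 cultures received. In the wild-type library the Ighg3 and Ighg2b units, whose germline transcription LPS induces, held 205 and 106 normalized RPM, and the Ighg1 and Ighe units, which IL-4 induces, held 8.30 and 3.97. In the knockout library the same units held 92.3, 51.7, 5.77 and 4.94. Reads on chromosome Y were 2688 in the knockout and 2159 in the wild-type library, and the annotated Xist promoter windows held 1 and 0 reads.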
